A study of Rattus norvegicus with 15 samples.

How the data were processed

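Liver total RNA of 15 male Sprague-Dawley rats was labelled with biotin in the Affymetrix 1-cycle protocol, per the labels, and hybridised to 1-channel rat expression arrays. The rats were 4 weeks old and had 5 days of adaptation before 14 days on diets with 2 g/kg genistein, 2 g/kg daidzein or neither, with 5 arrays per diet that the titles call biological replicates. Arrays are named by diet and the replicate number of their titles. The only values used were the table of 31099 probe sets in 15 arrays that the authors deposited. The unit of the deposited values is a score, a standardized log signal per array, which differs from the linear or log2 signal that the fixed design assumed. This was inferred from the values: after exponentiation with 1 scale per array, 380 of 380 gaps between often repeated values were whole numbers of steps within 0.001, as whole-number intensities minus a background would give. How the authors corrected the background, summarised the probes and chose the scale is not given in the sources used here. The scale was 2.60 log2 units per deposited unit on average and ranged from 2.54 (daidzein 4) to 2.79 (control 1). Values were multiplied by the common factor, so log2 changes are on a scale that depends on this inference, and changes of dim probe sets depend on the background that was subtracted. The zero of the level scale is arbitrary. Of the values, 260 in 97 probe sets were missing, none of them in a tested probe set.

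Array medians of the deposited values ranged from 0.00111 (genistein 5) to 0.127 (control 1), a difference over the limit of 0.1 that the design had fixed, so the arrays were quantile normalized (limma 3.58.1, R 4.3.3). The 57 control probe sets were left out, and the 18625 probe sets at or above the 40th percentile of mean level, among the 31042 others, were tested. A model with 3 groups was fitted with lmFit and eBayes over all 15 arrays, with 12 residual and 2.58 prior degrees of freedom, and each of the 3 comparisons was adjusted by Benjamini-Hochberg over the 18625 probe sets, with a threshold of 0.05. This model's adjusted p is printed as adjusted p, and SE and confidence intervals come from the same fit, while SD is that of the 5 arrays. Symbols came from the array annotation: 20832 probe sets had 1 symbol, 436 several and 9780 none, and 20764 were matched to the current rat gene table. A gene with several probe sets was represented by 1, that with the highest mean level over all arrays, which gave 10745 genes. The array annotation names no genome build, so no coordinates are given.

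Before the data were examined, 26 gene lists and 9 marker lists were written from general knowledge, and the groups, comparisons, thresholds, alternatives and naming rule were fixed. The rule names up to 10 rises and 10 falls of the largest size among called genes with 1 symbol whose 5 arrays all lay beyond the other group's mean, skipping predicted loci. It also names up to 4 genes of lowest p in each list that passed, and 22 genes chosen in advance, of which 14 were measured here and the others are not analysed here. Hao2 was named after its values were seen. Lists with at least 4 measured genes were tested with camera (limma) with a preset correlation of 0.01 and again with an estimated correlation, and adjusted over 34 lists. The adipocyte list had 2 measured genes and was not tested; its medians were -0.01 for genistein and -0.09 for daidzein against control, and 0.08 between them. Runs with several normalizations were looked at while the unit was being worked out, and the normalization reported is that of the fixed rule.

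The steps were tested on simulated data, drawn as independent normal noise with the mean and spread of each probe set, with 100 probe sets moved by 1 and 100 by 2 log2 units. They recovered 83, 86 and 85 of the former and 97, 96 and 95 of the latter for genistein against control, daidzein against control and genistein against daidzein, with 7, 8 and 12 false calls. A simulated shift of 0.5 in 1 list was recovered with 0 other lists passing. In 100 regroupings of the residuals of the real arrays, the preset correlation passed 3.4 lists on average and at least 1 list in 93, and the estimated correlation passed none.

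Array measures (3'/5' ratios, medians and principal components) were compared by two-sided exact permutation tests over 252 arrangements. Numbers in titles might pair the arrays of different diets, so this was checked on the residuals: 1 of 15 pairs of arrays with the same number correlated above 0.1 (r from -0.163 to 0.109). By the numbers in the descriptions, which differ from the titles in 9 arrays, 0 of 8 such pairs did (r from -0.0980 to 0.0734, a check added after seeing the data). A block of title numbers was therefore used only as an alternative. The correlation of both effects was compared with 100 shuffles of the residuals of the real arrays between the diets, and with 10 splits of the control arrays. Other alternatives were the values as deposited, a median shift, no filter or a 60th percentile filter, eBayes with trend and robust, arrayWeights, only the 10 arrays compared, 1 probe set per gene, the probe set of largest variance for lists, and each array left out in turn. Chosen after seeing the data were 3 more: each array converted by its own factor, 16 added to the intensities above background rebuilt from the scores, and control 1 and daidzein 5 both left out. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the scale and the figures.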

Results

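Liver RNA from 15 male Sprague-Dawley rats was measured on a 1-channel Affymetrix rat expression array, with 1 array per animal as the titles describe them. The descriptions carry other numbers than the titles for 9 of the 15 arrays, and that of genistein 3 ends in "-re", which is not explained. The rats ate a diet with 2 g/kg genistein, a diet with 2 g/kg daidzein or an isoflavone-free control diet for 14 days, with 5 animals per diet. Every diet held 200 g/kg casein and 100 g/kg palm oil. Genistein and daidzein are soy isoflavones, and genistein carries 1 more hydroxyl group. The study asks how the pair compare in their effects on hepatic lipid metabolism. Levels and changes are given in log2 units rebuilt from the deposited scores. Pearson correlations between arrays, across the 18625 probe sets tested, lay between 0.931 and 0.969, and the principal components with the largest shares held 16.2% and 10.9% of the variance. Among 18 two-sided exact permutation comparisons of array measures, the lowest p was 0.0238, for the Gapdh 3'/5' ratio (daidzein minus control -0.0708) and for PC2 (genistein minus control -23.1), with a Benjamini-Hochberg adjusted p of 0.214 for both. The number of arrays limits the precision of every value given here.

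The comparison of genistein with control asks what genistein did to the liver. Sult2a6, a hydroxysteroid sulfotransferase (Entrez gene 24902), was 13.5-fold higher with genistein, at 5.79 ± 0.78 against 2.04 ± 0.96 (mean ± SD, n = 5 per group, limma adjusted p = 0.00891). Hsd3b5, a hydroxysteroid dehydrogenase of the male liver (Entrez gene 24470), was 12.3-fold lower, at 2.32 ± 2.05 against 5.95 ± 0.37 (SD, n = 5, limma adjusted p = 0.0481). Dhrs7l1, of the dehydrogenase and reductase family (Entrez gene 299131), was 26.7-fold lower, at 1.33 ± 2.11 against 6.07 ± 0.16 (SD, n = 5, limma adjusted p = 0.0159). Its genistein arrays ranged from -0.61 to 4.51. The fit assumes the same spread in each diet, which the SDs of Hsd3b5 and Dhrs7l1 do not show, so their adjusted p may be too small. Cyp2a1, a steroid-hydroxylating cytochrome P450, was 3.09-fold higher (log2 change 1.63 ± 0.23 SE, adjusted p = 0.0102). Csad, the decarboxylase of taurine synthesis, fell by 1.29 on the log2 scale (SE 0.18, adjusted p = 0.0102), and Dmxl2, a vesicle protein, fell by 2.19 (SE 0.27, adjusted p = 0.00891). Akr1d1, a steroid reductase of bile acid synthesis, was 2.00-fold higher (log2 change 1.00 ± 0.15 SE, adjusted p = 0.0159).

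The other genes named by the fixed rule that rose with genistein were Akr1b7, an aldo-keto reductase (25.2-fold, adjusted p = 0.0455), Fmo5, a flavin monooxygenase (6.81-fold, 0.0198), and Prlr, the prolactin receptor (5.57-fold, 0.0340). Pcdh10, a protocadherin, rose 4.48-fold, Aldh1a1, a retinal dehydrogenase, 3.30-fold, Rgs3, a regulator of G protein signalling, 2.82-fold, and Ppp2r1b, a phosphatase subunit, 2.75-fold. Ugt2b34l1, a glucuronosyltransferase, rose 2.56-fold and Cyp2c6v1, a drug-metabolising cytochrome P450, 1.43-fold. Those that fell were Slc22a8, an organic anion transporter (5.93-fold lower on 1 of its 2 called probe sets, adjusted p = 0.0302), and Ust5r, an organic ion carrier (5.78-fold lower, 0.0450). Olr59, an olfactory receptor, was 3.06-fold lower, Nox4, an NADPH oxidase, 2.77-fold, Omd, osteomodulin, 2.48-fold, and Cd46, a complement regulator, 2.35-fold. The adjusted p of these 15 genes lay between 0.0126 and 0.0496. In each of them all 5 genistein arrays lay beyond the control mean, which the naming rule itself requires of genes not named through a list. For Pcdh10 (control mean -1.54), Nox4 (genistein mean -0.41) and Cd46 (genistein mean -1.01), a group lay below the filter level of -0.30, so these folds depend on the background that was subtracted: with 16 added to the rebuilt intensities they were 2.54, 2.14 and 1.72, with the calls kept. Akr1b7 also lay below that level in control 1 (-2.20), control 2 (-1.13) and control 4 (-0.88), so its fold depends on the background as well.

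Genistein changed 60 of 18625 probe sets against control, 28 higher and 32 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and by the probe set that represents each gene these were 36 genes, 17 higher and 19 lower. Without adjustment 2040 probe sets had p under 0.05, where chance alone would give 931. Sult2a6 and Dmxl2 kept their calls in each of the 10 fits that left out 1 array, and the other 20 called genes named here lost theirs in at least 1. The count fell to 5 without control 3, 10 without control 1, 14 without genistein 2, 17 without control 2, 17 without genistein 3, 19 without control 4 and 34 without genistein 1, and it was 203 without genistein 4. All these fits take part of their error from the third diet: with only the 10 arrays compared limma called 0 (1896 had an unadjusted p under 0.05, and the lowest adjusted p was 0.05004). The log2 changes are the same in that fit by construction, as the group means do not change. The count was 17 with the replicate numbers as a block and 4 without both control 1 and daidzein 5.

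The lists of sex-biased liver genes moved in opposite directions with genistein. The 14 measured male-predominant genes had a median log2 change of -0.87, and 12 of the 14 were lower (limma camera, adjusted p = 3.38e-08). The adjusted p was 0.315 with an estimated correlation. Hsd3b5 and Ust5r were called lower, none higher, and adjusted over the list alone 10 were lower and 1 higher. Obp3, a male lipocalin, had an adjusted p of 0.0656 on the probe set that stands for it (log2 change -4.14 ± 0.88 SE), while another of its probe sets was called lower. Cyp3a18 was lower without being called (log2 change -1.81 ± 0.43 SE, adjusted p = 0.0909). Akr1c14, a member of the male list, went the other way (log2 change 0.63 ± 0.14 SE, adjusted p = 0.0729), and 2 other probe sets of it were called higher. The 14 female-predominant genes had a median of 0.60 (camera adjusted p = 1.70e-04, and adjusted p = 0.144 with an estimated correlation). Of these, Sult2a6, Prlr and Cyp2a1 rose and Slc22a8 fell. Adjusted over the list alone 7 were higher and 2 lower, the latter Slc22a8 and Hao2, a hydroxyacid oxidase (log2 change -0.93). Cd36, the fatty acid translocase of the same list, had a log2 change of 1.58 ± 0.37 (SE, adjusted p = 0.0851). Both sex lists were written from general knowledge and could not be checked here, as all rats were male. Whether Slc22a8 and Akr1c14 stand in the right list is therefore not known. Over the alternatives the male median ranged from -1.18 to -0.51 and the female median from 0.39 to 1.12; the values nearest 0 were those without genistein 3 (-0.51 and 0.39). Male list medians per array, relative to the control mean, were -0.89, -0.78, -1.89, -0.22 and -0.46 for genistein 1 to 5. Those of the female list were 0.94, 1.01, 1.41, -0.03 and 0.61, so genistein 4 showed no rise in it and lay within the controls (-0.12 to 0.14).

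**Figure D1:**
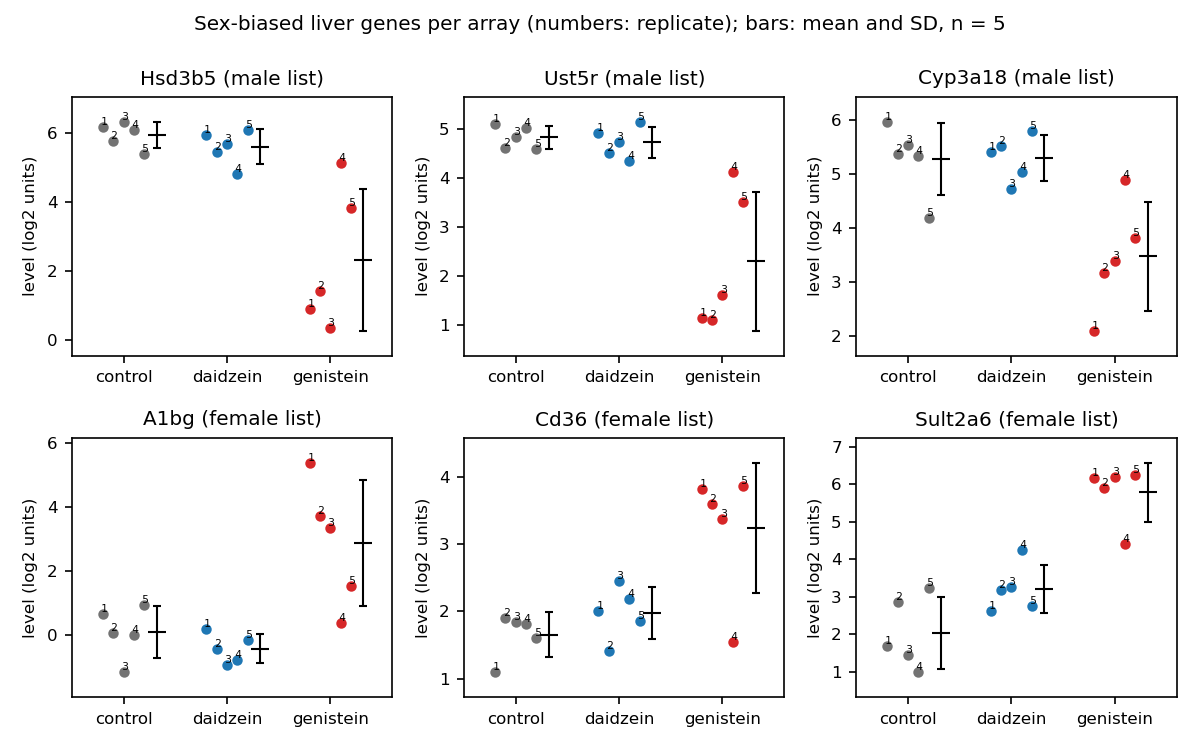
Log2 level of 3 male-predominant genes (Hsd3b5, Ust5r, Cyp3a18) and 3 female-predominant genes (A1bg, Cd36, Sult2a6) in each array, by diet, with mean and SD (n = 5) beside the points. Hsd3b5 stood at 5.39 or above in every control array and at 0.90, 1.41, 0.34, 5.13 and 3.81 in genistein 1 to 5.

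Among lipid lists, the cholesterol synthesis genes had a median log2 change of -0.29 with genistein, and 18 of 20 were lower (camera adjusted p = 3.20e-05, and adjusted p = 0.675 with an estimated correlation). None of the 20 was called; adjusted over the list alone 1 was lower. The sterol enzymes Msmo1 (log2 change -0.81 ± 0.19 SE, adjusted p = 0.0905), Sqle (-0.55), Mvd (-0.52) and Nsdhl (-0.25) had the lowest p. The fatty acid synthesis list had a median of -0.15, with 16 of 20 lower (camera adjusted p = 0.0114, and adjusted p = 0.704 with an estimated correlation), and 0 called over all or adjusted over the list alone. This call was lost without control 2 (adjusted p = 0.112), genistein 3 (0.208) or genistein 5 (0.156), where the median was -0.10, -0.06 and -0.08; it was -0.10 without control 3 and -0.23 without genistein 2. The lipogenic genes Mid1ip1 (log2 change -0.97), Fasn (-0.89 ± 0.39 SE, adjusted p = 0.425), Acly (-0.85 ± 0.33, 0.354) and Srebf1 (-0.65 ± 0.32, 0.481) were not called, nor were Elovl5 (-0.22), Me1 (-0.16), Acaca (-0.11) or Scd (0.07). Genistein 3 carried much of the lipogenic values, which without it were -0.47 for Fasn, -0.48 for Acly and -0.42 for Srebf1.

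Peroxisomal and other PPAR alpha targets had a median of 0.14 with genistein, and 21 of 28 were higher (camera adjusted p = 0.00764, and adjusted p = 0.536 with an estimated correlation). None was called; adjusted over the list alone 2 were higher and 1 lower. The call was lost without control 3 (adjusted p = 0.0588) or genistein 1 (0.135, with a median of 0.07). Cd36, given above with the female list, also stands in this list and was not called, so the lists are not independent. Ehhadh, a peroxisomal oxidation enzyme (log2 change 0.39, adjusted p = 0.206), Cpt1a, the mitochondrial carnitine transferase (0.47, 95% confidence interval 0.10 to 0.84, adjusted p = 0.318), Cyp4a1, a fatty acid hydroxylase (0.46), and Cpt1b (-0.39) and Decr2 (-0.22) were not called. The bile acid and sterol transport list had a median of 0.17, with 12 of 16 higher (camera adjusted p = 8.60e-04, and adjusted p = 0.526 with an estimated correlation); Akr1d1 was called and, adjusted over the list alone, 5 were higher; without control 1 the median was 0.09. The transporters Abcc2 (0.50), Abcb4 (0.45) and Slco1b2 (0.44) were not called, nor was Cyp7a1, the cholesterol hydroxylase of bile acid synthesis (log2 change -0.16, interval -1.36 to 1.04). Mitochondrial fatty acid oxidation (median 0.01), triacylglycerol synthesis (median 0.05, mean -0.01) and the apolipoproteins (median -0.00, mean 0.05) had a camera adjusted p of 0.979 each, with 0 called adjusted over the list alone. Cpt2 (0.09), Hadha (-0.03) and Pck1 (-0.13) were also not called.

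The targets of the xenobiotic receptors CAR and PXR had a median of 0.36 with genistein, with 14 of 18 higher (camera adjusted p = 1.39e-04, and adjusted p = 0.185 with an estimated correlation). Aldh1a1, Cyp2a1 and Cyp2c6v1 rose. Adjusted over the list alone 6 were higher and 2 lower, and Cyp2a1, Cyp2c7, Cyp3a2 and Cyp3a18 were among the genes that also stood in the sex lists. The median was 0.23 without genistein 3 and 0.23 without genistein 5. The Nrf2 targets did not pass with genistein (median -0.06, mean 0.06, camera adjusted p = 0.979; adjusted over the list alone 2 were higher and 2 lower), and Nqo1, a quinone reductase, had a log2 change of 0.78 ± 0.40 (SE, adjusted p = 0.510), or 0.40 without control 1. In all, 7 of 34 lists passed, 4 higher and 3 lower, and 0 with an estimated correlation. The preset correlation passed lists freely here: in 100 regroupings of the residuals it passed 3.4 of 34 lists on average and at most 9, and the estimated correlation passed 0.

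**Figure D2:**
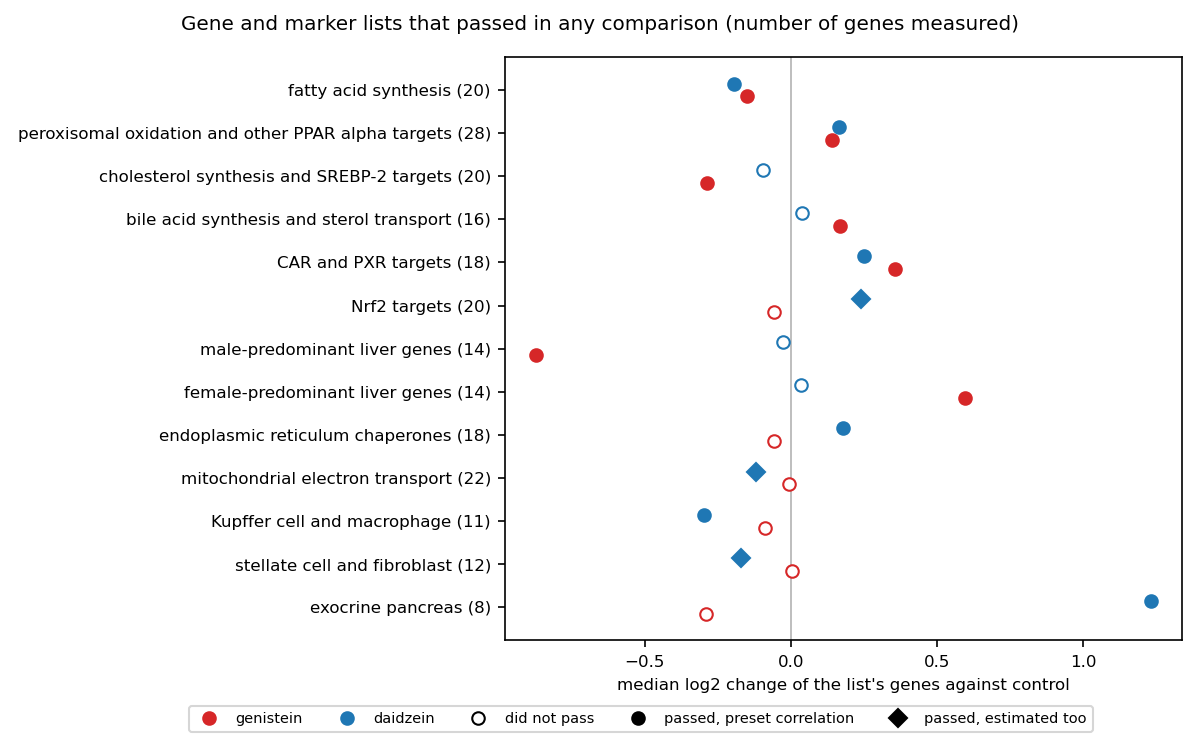
Median log2 change against control of each gene or marker list that passed in any comparison, for genistein and daidzein, with the number of genes measured in brackets. Filled points passed camera with the preset correlation, open points did not, and diamonds passed with an estimated correlation too; the daidzein diamonds are the Nrf2 targets (0.24), electron transport (-0.12) and stellate cell markers (-0.17).

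The comparison of daidzein with control asks the same of daidzein. Akr7a3, the aflatoxin aldehyde reductase (Entrez gene 26760), was 4.40-fold higher with daidzein, at 5.67 ± 0.21 against 3.53 ± 0.21 (SD, n = 5 per group, limma adjusted p = 2.43e-05). Gsta3, a glutathione S-transferase (Entrez gene 494500), was 10.8-fold higher, at 2.65 ± 0.34 against -0.79 ± 0.62 (SD, n = 5, limma adjusted p = 0.00186). Ephx1, the microsomal epoxide hydrolase (Entrez gene 25315), was 1.73-fold higher, at 6.81 ± 0.17 against 6.02 ± 0.16 (SD, n = 5, limma adjusted p = 0.0453). The control mean of Gsta3 lay below the filter level, and with 16 added to the rebuilt intensities its fold was 6.66, with the call kept. All 3 are Nrf2 targets by the fixed list, and in each all 5 daidzein arrays lay above every control array. Nqo1, of the same list, was 3.63-fold higher without being called (log2 change 1.86 ± 0.40 SE, adjusted p = 0.228). These 3 probe sets, all higher, were the whole count (limma, Benjamini-Hochberg over 18625); 1536 had an unadjusted p under 0.05, where chance would give 931. Akr7a3 and Gsta3 kept their calls in each of the 10 fits that left out 1 array, Ephx1 only in that without daidzein 2, and the count was 8 without daidzein 1.

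The 20 Nrf2 targets had a median log2 change of 0.24 with daidzein, and 15 were higher (camera adjusted p = 2.13e-08, and adjusted p = 0.00595 with an estimated correlation). Of these, 3 were called higher and none lower; adjusted over the list alone 9 were higher. The CAR and PXR targets had a median of 0.25, with 13 of 18 higher (camera adjusted p = 0.00143, and adjusted p = 0.217 with an estimated correlation); Ephx1, which stands in both lists, was called and, adjusted over the list alone, 3 were higher. The median was 0.13 without control 3. Of that list Aldh1a1 (log2 change 1.35, adjusted p = 0.238), Nr1i3, the receptor CAR itself (0.67), and Cyp2c6v1 (0.30) were not called.

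**Figure D3:**
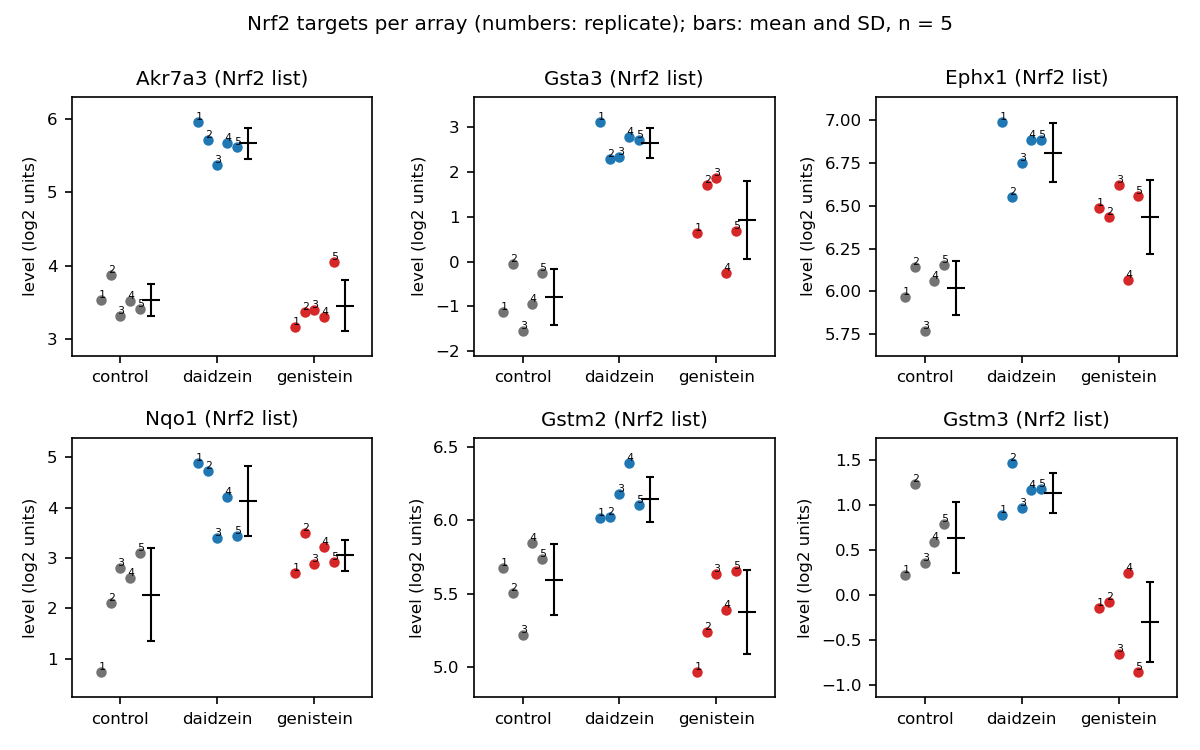
Log2 level of 6 Nrf2 targets (Akr7a3, Gsta3, Ephx1, Nqo1, Gstm2, Gstm3) in each array, by diet, with mean and SD (n = 5) beside the points. Akr7a3 stood between 5.38 and 5.96 in the daidzein arrays, and between 3.17 and 4.05 in all others.

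The PPAR alpha targets had a median of 0.16 with daidzein, with 23 of 28 higher (camera adjusted p = 0.00357, and adjusted p = 0.373 with an estimated correlation). None was called; adjusted over the list alone 2 were higher, and the median was 0.09 without control 1. Ehhadh (log2 change 0.46 ± 0.12 SE, adjusted p = 0.346), Ucp3, an uncoupling protein (0.50), Vnn1, a pantetheinase (0.61), Cyp4a1 (0.47) and Cpt1a (0.24) were not called. The fatty acid synthesis list had a median of -0.19, with 15 of 20 lower (camera adjusted p = 0.0262, and adjusted p = 0.788 with an estimated correlation), and 0 called over all or adjusted over the list alone. That call was lost without control 2 (adjusted p = 0.189), daidzein 3 (0.0559) or daidzein 5 (0.0699), and with the values as deposited (0.124). Mlxipl, the carbohydrate response factor (log2 change -0.33), Elovl5 (-0.24), Elovl6 (-0.58), Srebf1 (-0.62), Acly (-0.44), Fasn (-0.33 ± 0.39 SE, adjusted p = 0.865), Acaca (-0.17), Scd (-0.05) and Me1 (0.26) were not called. Fasn was at -0.53 without control 5 and -0.22 without daidzein 5, and Acly at -0.29 without daidzein 5. Cholesterol synthesis (median -0.10, adjusted p = 0.489), the bile acid list (0.04, 0.296), mitochondrial fatty acid oxidation (median -0.01, mean 0.03, 0.985), triacylglycerol synthesis (median -0.02, with camera's direction up, 0.887), the apolipoproteins (-0.02, 0.856), the male list (median -0.03, with camera's direction up, 0.902) and the female list (0.04, 0.625) did not pass, with 0 called adjusted over the list alone. Cyp7a1 (-0.02), Cpt2 (0.09), Hadha (-0.07) and Pck1 (0.08) were not called.

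**Figure D4:**
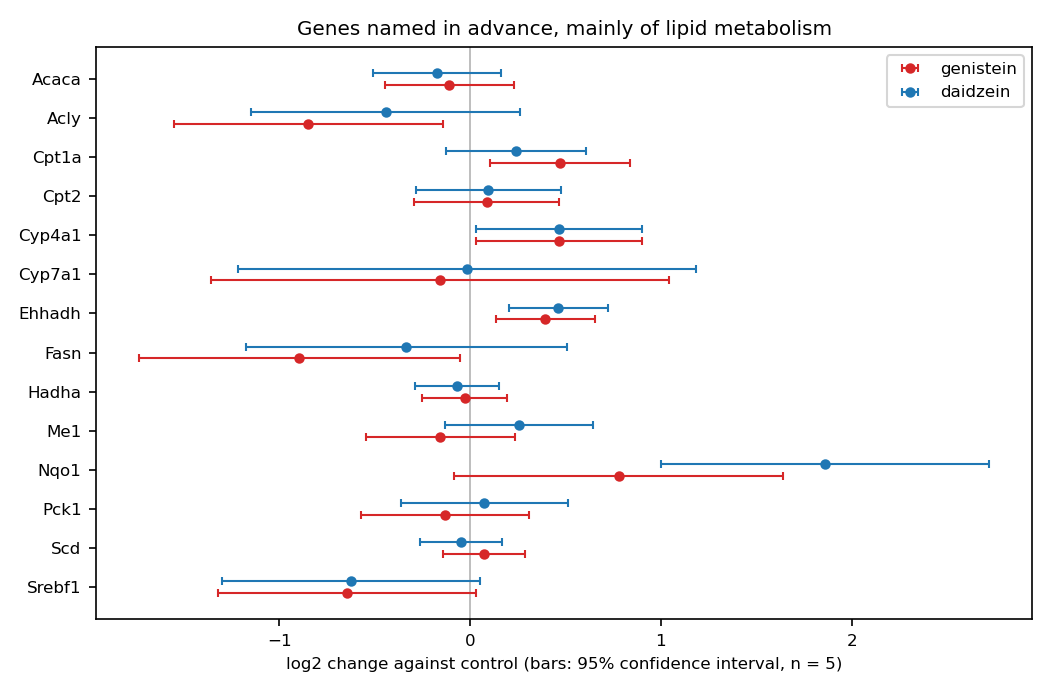
Log2 change against control, with its 95% confidence interval (n = 5 per group), of the 14 measured genes that were named in advance, most of them genes of lipid metabolism, for genistein and daidzein. None passed adjustment; Fasn stood at -0.89 (-1.74 to -0.05) with genistein and -0.33 (-1.18 to 0.51) with daidzein.

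The endoplasmic reticulum chaperones had a median of 0.18 with daidzein, with 16 of 18 higher (camera adjusted p = 0.00143, and adjusted p = 0.497 with an estimated correlation). Dnajb9 (0.46), Manf (0.26), Pdia3 (0.23) and Canx (-0.16) had the lowest p, and 0 were called over all or adjusted over the list alone; without daidzein 2 the median was 0.12. The electron transport list had a median of -0.12, with 19 of 22 lower (camera adjusted p = 5.01e-04, and adjusted p = 0.0387 with an estimated correlation). Cox6c (-0.25), Uqcrc2 (-0.33), Ndufa4 (-0.16) and Ndufv1 (-0.15) were among them, 0 were called over all or adjusted over the list alone, and the list passed neither as deposited (adjusted p = 0.109) nor after a median shift (0.177).

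Several cell marker lists moved with daidzein. Stellate cell and fibroblast markers had a median of -0.17, with 10 of 12 lower (camera adjusted p = 0.00277, and adjusted p = 0.0387 with an estimated correlation). Sparc (-0.31), Dcn (-0.76), Reln (-0.34) and Col3a1 (-0.30) had the lowest p; 0 were called, and adjusted over the list alone 4 were lower. Kupffer cell and macrophage markers had a median of -0.30, with 10 of 11 lower (camera adjusted p = 5.01e-04, and adjusted p = 0.373 with an estimated correlation); Mrc1 (-0.27), Adgre1 (-0.47), C1qc (-0.31) and C1qa (-0.34) had the lowest p, and 0 were called over all or adjusted over the list alone. The 8 exocrine pancreas markers had a median of 1.23 (camera adjusted p = 0.0262, and adjusted p = 0.921 with an estimated correlation). The daidzein 5 array carried this: its list median was 6.35 above the control mean against at most -0.01 in the other 4 daidzein arrays. Without daidzein 5 the list's median change was -0.12 (adjusted p = 0.397), and the call was also lost without control 4 (0.0602) or control 5 (0.0558). Cpb1 (1.49), Cela2a (1.47), Cpa1 (1.24) and Cel (1.03), all digestive enzymes, were not called. Hepatocyte markers had a median of -0.00 (camera adjusted p = 0.902). Their list median was exactly 0 in control 1 and in daidzein 1, 3, 4 and 5. Quantile normalization can give such ties, as it gives equal ranks equal values. This median therefore says little about hepatocyte content. In all, 9 of 34 lists passed, 5 higher and 4 lower, and 3 with an estimated correlation.

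**Figure D5:**
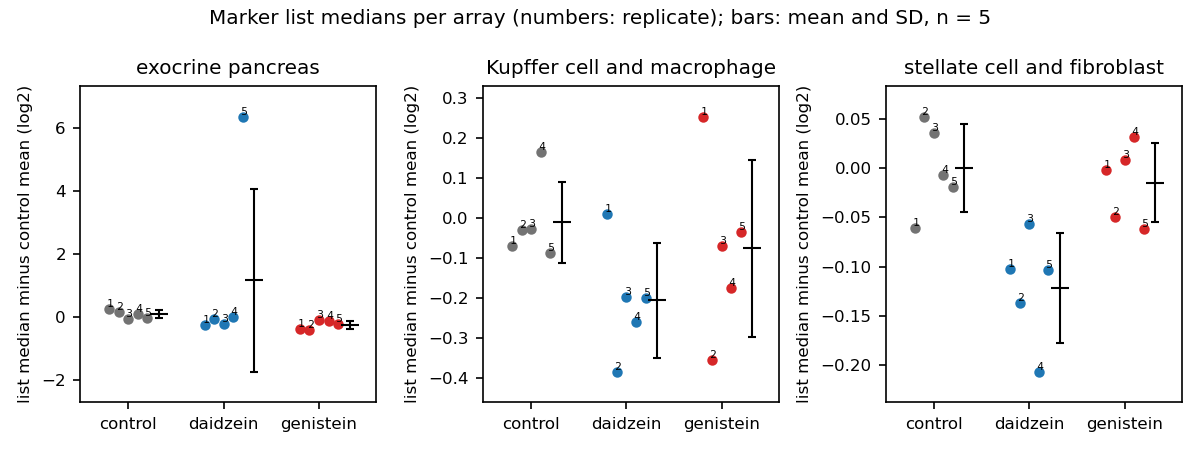
Median of the exocrine pancreas, Kupffer cell and stellate cell marker lists in each array, in log2 units relative to the control mean, by diet, with mean and SD (n = 5) beside the points. The exocrine pancreas median was 6.35 in daidzein 5 and at most -0.01 in the other daidzein arrays.

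The comparison of genistein with daidzein sets the isoflavones against each other at the same dose and duration, where the structures differ by 1 hydroxyl group. Akr7a3 was 4.63-fold lower with genistein, at 3.46 ± 0.34 against 5.67 ± 0.21 (SD, n = 5 per group, limma adjusted p = 1.52e-05). Apon, apolipoprotein N (Entrez gene 304603), was 1.83-fold lower, at 4.74 ± 0.14 against 5.62 ± 0.09 (SD, n = 5, limma adjusted p = 3.47e-04). Csad was 2.77-fold lower (log2 change -1.47 ± 0.18 SE, adjusted p = 0.00612). The glutathione S-transferases Gstm1 (log2 change -0.49 ± 0.07, adjusted p = 0.0140) and Gstm3 (-1.43 ± 0.22, 0.0192) were lower with genistein; the genistein mean of Gstm3 lay below the filter level, and its change was -1.08 with 16 added to the rebuilt intensities, with the call kept. Also lower were Isyna1, the inositol phosphate synthase (1.72-fold), Nucb2, a calcium-binding protein (2.11-fold), Mab21l3 (log2 change -0.68), Dhrs7l1 (24.4-fold), Poteml2 (7.20-fold) and Slc22a8 (6.06-fold), with adjusted p from 0.0192 to 0.0398. The genistein arrays spread more widely than the daidzein arrays for Dhrs7l1 (-0.61 to 4.51 against 5.24 to 6.67) and Slc22a8 (1.56 to 4.65 against 4.99 to 5.34). The adjusted p of Dhrs7l1 and Slc22a8 may therefore be too small. Higher with genistein were Plaat3, a phospholipase and acyltransferase (2.79-fold, adjusted p = 0.0344), Oat, the ornithine aminotransferase (1.99-fold, 0.0328), and Mpc1, a subunit of the mitochondrial pyruvate carrier (1.55-fold, 0.0192). In all 14 genes the 5 genistein arrays lay beyond the daidzein mean, which the naming rule itself requires of genes not named through a list.

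These genes belong to 21 of 18625 probe sets that differed, 6 higher and 15 lower with genistein (limma, Benjamini-Hochberg), and by the probe set that represents each gene 3 genes were higher and 12 lower; 1746 had an unadjusted p under 0.05, where chance would give 931. Akr7a3, Apon and Csad kept their calls in each of the 10 fits that left out 1 array, and the other 11 lost theirs in at least 1. The count was 3 without daidzein 3, 3 without genistein 2, 4 without daidzein 4, 4 without daidzein 5, 5 without genistein 1, 7 without daidzein 2 and 136 without genistein 4. It was 2 with only the 10 arrays compared, 2 with the replicate block and 4 without both control 1 and daidzein 5.

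The Nrf2 targets were lower with genistein than with daidzein, with a median difference of -0.31 and 15 of 20 lower (camera adjusted p = 1.64e-09, and adjusted p = 0.00398 with an estimated correlation). Akr7a3, Gstm1 and Gstm3 were called and, adjusted over the list alone, 9 were lower; Gstm2 was not called (log2 change -0.77 ± 0.14 SE, adjusted p = 0.0569). Male-predominant genes had a median difference of -1.03 (camera adjusted p = 1.33e-09, and adjusted p = 0.162 with an estimated correlation), with 0 called and, adjusted over the list alone, 9 lower and 1 higher; without genistein 3 the median was -0.57. Ust5r (-2.43), Hsd3b5 (-3.28), Obp3 (-3.79) and Cyp3a18 (-1.82) had adjusted p from 0.0755 to 0.110. Female-predominant genes had a median difference of 0.80 (camera adjusted p = 5.60e-04, and adjusted p = 0.0729 with an estimated correlation), with Slc22a8 called lower and, adjusted over the list alone, 8 higher and 2 lower. Sult2a6 (2.58 ± 0.47 SE, adjusted p = 0.0534), Cyp2a1 (1.17 ± 0.23, 0.0699) and A1bg, a plasma glycoprotein (3.29 ± 0.72, 0.0879), were not called.

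For lipid metabolism, the direct comparison gave a cholesterol synthesis median of -0.15, with 16 of 20 lower with genistein (camera adjusted p = 8.53e-04, and adjusted p = 0.762 with an estimated correlation); 0 were called and, adjusted over the list alone, 1 was lower. The call was lost without genistein 3 (adjusted p = 0.0520). Dhcr7 (-0.75), Msmo1 (-0.55), Sqle (-0.44) and Mvk (-0.17) had the lowest p. The bile acid list had a median difference of 0.15 (camera adjusted p = 0.0209, and adjusted p = 0.709 with an estimated correlation), with Akr1d1 (0.53), Abcc2 (0.41), Slco1b2 (0.38) and Abcb4 (0.31) not called and 0 called over all or adjusted over the list alone. Leaving out any of 6 arrays ended that call: daidzein 1 (adjusted p = 0.0561), daidzein 2 (0.0515), daidzein 3 (0.0611), genistein 3 (0.167, median 0.07), genistein 4 (0.0752, median 0.08) and genistein 5 (0.0560). The lists of fatty acid synthesis (median 0.00, mean -0.09, adjusted p = 0.822), PPAR alpha targets (0.07, 0.888), mitochondrial fatty acid oxidation (-0.00, 0.888), triacylglycerol synthesis (median 0.01, with camera's direction down, 0.888) and the apolipoproteins (0.05, 0.649) did not shift past the threshold in either direction. Adjusted over the list alone, 1 PPAR alpha target was higher and 2 lower, 1 triacylglycerol gene was higher and 2 lower, and 0 were called in the other three. The 95% confidence intervals of single lipid genes bound the difference as follows. Fasn lay between -1.40 and 0.28, Acly between -1.11 and 0.30, Srebf1 between -0.70 and 0.65, Acaca between -0.27 and 0.40, Scd between -0.10 and 0.34, and Me1 between -0.80 and -0.02 (adjusted p = 0.507). Without genistein 3 the differences were -0.14 for Fasn and -0.03 for Acly, against -0.56 and -0.41 with it. Cpt1a lay between -0.14 and 0.60, Cpt2 between -0.39 and 0.37, Hadha between -0.18 and 0.26, Ehhadh between -0.33 and 0.19, and Cyp4a1 between -0.44 and 0.43. Cyp7a1 lay between -1.34 and 1.06, Pck1 between -0.64 and 0.23, and Nqo1 between -1.94 and -0.22 (adjusted p = 0.393).

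The other lists that passed in the direct comparison were the endoplasmic reticulum chaperones (median -0.20, camera adjusted p = 5.04e-05, and adjusted p = 0.286 with an estimated correlation), where Pdia3 (-0.39), Sdf2l1 (-0.52), Dnajb11 (-0.29) and Pdia6 (-0.23) had the lowest p, and stellate cell markers (median 0.15, camera adjusted p = 0.00235, and adjusted p = 0.0497 with an estimated correlation), with Col3a1 (0.32), Col1a2 (0.24), Reln (0.27) and Lrat (0.26) among them. Electron transport (median 0.08, adjusted p = 0.0167, and adjusted p = 0.179 with an estimated correlation) was higher with genistein, with Ndufa5 (0.98), Cox6c (0.26), Ndufs3 (0.14) and Atp5f1b (0.15) having the lowest p. It passed neither as deposited (adjusted p = 0.694) nor after a median shift (0.669), nor without daidzein 4 (0.0709) or genistein 1 (0.0540). Kupffer cell markers (median 0.20, adjusted p = 0.00982, and adjusted p = 0.709 with an estimated correlation) included Mrc1 (0.21), Cd5l (0.40), C1qc (0.21) and Cd163 (0.34), and did not pass without daidzein 2 (0.0580, median 0.13) or genistein 1 (0.172, median 0.12). Exocrine pancreas markers (median -1.43, adjusted p = 0.00542, and adjusted p = 0.768 with an estimated correlation), with Cela1 (-0.88), Cel (-1.47), Ctrb1 (-1.76) and Cela2a (-1.88), did not pass without daidzein 5 (0.652, median -0.08). None of these 5 lists held a called gene; adjusted over the list alone 2 chaperones were lower and 1 stellate marker higher, and 0 in the other three. CAR and PXR targets did not differ past the threshold (median 0.18, mean -0.01, adjusted p = 0.477; adjusted over the list alone 2 were higher and 3 lower). In all, 10 of 34 lists passed, 5 higher and 5 lower, and 2 with an estimated correlation.

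Effects of both isoflavones share the control arrays, so their correlation across genes has a part that comes from those arrays. Across the 18625 probe sets Pearson's r of the log2 changes was 0.480. Residuals of the real arrays, shuffled between the diets, gave 0.505 on average (0.182 to 0.776). Genes are not independent replicates. With the controls split so that each isoflavone had its own, the median r was 0.0973 (0.0386 to 0.180). No probe set was called in both comparisons in the same direction (limma), where 0.00451 higher would be the number by chance. Akr7a3, called with daidzein, was at 3.46 ± 0.34 with genistein against 3.53 ± 0.21 in controls (SD, n = 5). Gsta3 and Ephx1, also called with daidzein, were higher with genistein than in controls without being called. Their log2 changes were 1.72 (limma adjusted p = 0.0745) and 0.41 (0.169).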

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

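The tests of genistein 4 as a control and of how often it lay beyond the controls, of the scaling, of a diet effect on pancreatic genes, of the number of raised pancreatic genes and the 3 on the Nrf2 targets were chosen only after the result was seen. A sample was picked out where its gap to the nearest of its group of 5 was over Dixon's 95% limit. This happened in 30 of 435 groups, where chance flags about 1 in 20 groups, or 21.8 here. Daidzein 5 had 8 of the 30 and genistein 4 had 5. The genistein 4 test was revised after its value had been seen: in its earlier form each control counted in its own group's mean, and the highest control was then at 0.192.

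With genistein, the male list shifted lower and the female list higher under the preset correlation only (adjusted p = 0.315 and 0.144 with an estimated one), with 2 genes of the male list called lower and genes of the female list called both higher (3) and lower (1). The lower one was Slc22a8, whose place in the female list was not checked. Genistein 4 was the lowest of its group for Sult2a6 (gap ratio 0.814; level 4.41, the nearest genistein array 5.91, the highest control 3.23), Cyp2c6v1 (0.869; 7.69, 7.76 and 7.40) and Cd36 (0.787; 1.54, 3.37 and 1.90), and so lay above every control in the former pair and among the controls in Cd36, while its female list median (-0.03) lay within the controls (-0.12 to 0.14) and its male one (-0.22) below the lowest (-0.06). Female animals among those labelled genistein are excluded by Y-linked genes, whose lowest genistein array lay 0.262 log2 above the lowest control array, and by Xist, whose highest genistein array lay -0.09 from the highest control array, and the scaling between arrays is excluded as the whole cause, since other scalings moved the male median by at most 5.06% of its size. A mislabelled control stays open for genistein 4: over the 178 probe sets outside the sex lists that were called without it, its median position between the controls (0) and the other genistein arrays (1) was 0.360, within the range of controls each placed against the rest (-0.108 to 0.371) though above 4 of 5. It lay beyond every control in 20 of the 22 called named genes, which were called with it included, and in 100 of the 178; on probe sets chosen without it and 1 control, it lay beyond the other 4 controls in 108 to 135 of 178 and the control left out in 36 to 123, with control 5 nearest (123 against 135), so a true genistein animal with a weaker change could also lie there, and activation of CAR or PXR, whose list shares Cyp2a1, Cyp2c7, Cyp3a2 and Cyp3a18 with the sex lists, was not tested.

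In daidzein 5 the exocrine pancreas markers were high, with a list median 6.35 above the control mean and a gap ratio of 0.963. The ratio was 0.940 for Cel, 0.922 for Ctrb1, 0.892 for Cela1, 0.870 for Cela2a, 0.832 for Cpb1 and 0.807 for Cpa1, and against the mean of the other 14 arrays Prss1 stood 8.07 higher, Cela2a 7.45 and Pnlip 6.99. An effect of the diet is excluded as the whole cause, since the highest of the other 4 daidzein arrays was at -0.0139 relative to the control mean. Pancreatic tissue or RNA in this sample is a candidate source: in a second list of 25 pancreatic genes, 12 stood over 2 log2 units above the other arrays, with Pnliprp1 at 8.50, Clps at 6.39 and Ctrc at 6.20, and 0 did in any other array. The test set in advance, a second list median over 2, was missed at 1.997 and leaves this open, and the count was added afterwards; the labels name no step that would have removed such tissue.

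With daidzein, Nrf2 targets were higher. Signal shared between glutathione S-transferase paralogs is excluded as the whole cause: without these the remaining 14 genes had a median of 0.19 (camera p = 2.55e-05, and p = 0.00232 with an estimated correlation). Pancreatic RNA in daidzein 5 is excluded, as the list's adjusted p without that array was 1.13e-07 with 100.4% of its mean kept, and so are the low values of control 1, with 2.35e-08 and 95.8%. A direct or indirect effect of daidzein on this pathway may explain the change, as a hypothesis found and tested on the same data. Activation of CAR or PXR was not tested. Their list shares Ephx1 with the Nrf2 list and also passed higher with daidzein under the preset correlation.

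In the fit over all 15 arrays, splits of the 10 arrays tested the count of 60 probe sets changed by genistein. Only the real split gave as many (1 of 100, highest other 7). This argues against chance for the count as a whole, not for any single probe set. A split that mixes the diets also puts any diet difference into its error, which can lower its count. The splits do not exclude chance for the 7 lists of genistein (8 of 100, highest other 7). With only the 10 arrays compared limma called 0 of these probe sets (1896 at an unadjusted p under 0.05). The 22 called named genes had an adjusted p from 0.05004, the lowest of all, to 0.176. Their changes are differences of the same group means, so they could not move in that fit. The replicate block gave 17, and leaving out both control 1 and daidzein 5 gave 4. The splits were run in the fit over all 15 arrays alone. For the count of 3 probe sets changed by daidzein, only the real split gave as many (1 of 100, highest other 1). For its 9 lists 3 of 100 splits gave as many, under the limit set in advance. The highest other gave 10, so chance stays possible for these lists. The count of 21 probe sets that differed between isoflavones was also reached by the real split alone (1 of 100, highest other 1), again in that fit. Neither result covers any single probe set. For the 10 lists only the real split gave as many (1 of 100), though the highest other was 9. Both list counts used the preset correlation and include the exocrine pancreas list, which daidzein 5 carried. The 21 were 2 with only the 10 arrays compared, 2 with the replicate block and 4 without both arrays, and with an estimated correlation the 9 and 10 lists were 3 and 2.

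The other picked-out values were spread over arrays and are given without explanation. Genistein 4 was lowest for electron transport (0.7102) and highest for Decr2 (0.812), and genistein 5 was highest for Akr7a3 (0.740). Daidzein 5 was also highest for Nr1i3 (0.876). Daidzein 2 was lowest for cell cycle genes (0.772), hepatocyte markers (1, as the other 4 arrays tied), Lrat (0.896) and PC2 (0.729). Daidzein 1 was highest for Apon (0.719), Csad (0.715) and Cox6c (0.777). Control 2 was highest for cholangiocyte markers (0.841) and for erythroid and blood markers (0.935), and control 4 for triacylglycerol synthesis (0.755) and Kupffer cell markers (0.770). Control 5 was highest for Cox6c (0.810) and Cyp2a1 (0.745) and lowest for Elovl6 (0.776). Control 3 was lowest for Cd46 (0.761), and control 1 for Cd5l (0.711).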

How the results depend on the processing

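Converting each array by its own factor, adding 16 to the intensities rebuilt from the scores, and leaving out control 1 and daidzein 5 together, were chosen only after the result was seen. No named gene that was called reversed under any alternative, and the median of all genes lay within 0.02 of 0 under quantile normalization, as deposited and after a median shift. In every case below the cause was not tested, except that fewer arrays or fewer probe sets were tested where the alternative says so.

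The number of probe sets changed by genistein against control was 60. It was 34 after a median shift, 14 without a filter, 124 with the 60th percentile filter, 110 with trend and robust, 140 with arrayWeights, 0 with only the 10 arrays compared (limma), 17 with the replicate block and 4 without both control 1 and daidzein 5. Leaving out 1 array gave 5 to 203. As deposited it was 51, with 1 probe set per gene 43, with each array's own factor 60 and with 16 added 80. The own factor could hardly move any value, as the quantile normalization after it keeps only the ranks within each array. It therefore does not test the inferred scale. For daidzein the 3 became 7 with the 60th percentile filter, 6 with trend and robust, 7 with arrayWeights and 1 without both arrays, and leaving out 1 array gave 2 to 8. For genistein against daidzein the 21 became 9 after a median shift, 3 without a filter, 67 with the 60th percentile filter, 53 with trend and robust, 74 with arrayWeights, 2 with only the 10 arrays compared, 2 with the replicate block, 4 without both arrays and 35 with 16 added, and leaving out 1 array gave 3 to 136. It was 14 as deposited.

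The replicate block ended 13, 1 and 12 calls of named genes in the order of comparisons above and changed no list call. Probe sets changed the same way by both isoflavones were 0, and 2 with the 60th percentile filter, 1 with trend and robust, 2 with arrayWeights, and 0 to 2 without 1 array, the 2 being without genistein 4. The correlation of both effects stayed between 0.425 and 0.555 under every alternative run.

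With an estimated correlation the lists that passed fell from 7 to 0, from 9 to 3 and from 10 to 2. With other alternatives they lay between 6 and 8 for genistein, 7 and 10 for daidzein and 8 and 11 between isoflavones. The daidzein Nrf2 and stellate lists and the same lists between isoflavones passed under all 23 alternatives. Exocrine pancreas with daidzein reversed to -0.12 without daidzein 5 and to -0.0960 without both arrays (adjusted p = 0.397 and 0.516), reached 1.63 without daidzein 1, and did not pass with only the 10 arrays compared (0.0756). As deposited, fatty acid synthesis and electron transport with daidzein, and the bile acid list and electron transport between isoflavones, did not pass (adjusted p = 0.124, 0.109, 0.151 and 0.694), nor did they after a median shift (0.0678, 0.177, 0.254 and 0.669).

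Among called named genes, Akr7a3 passed under all 22 alternatives in both comparisons and Apon in its own. Of the 22 genistein genes none passed under all; 296 of 470 values kept the call. For daidzein 50 of 66 did and between isoflavones 180 of 308. Ephx1 had adjusted p from 0.0104 to 0.543. Adding 16 before the logarithm had been set for a linear table only and was run here on rebuilt intensities instead; it ended no call of a named gene or list. For dim probe sets the signal over background limits what can be seen, as the background subtracted by the authors is not given in the sources used here.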

Other observations

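Some called genes fall outside the naming rule and were chosen after their values were seen. Apon, the apolipoprotein that differed between the isoflavones, was also lower with genistein than in controls (log2 change -0.65 ± 0.08 SE, limma adjusted p = 0.00958). Egfr, the epidermal growth factor receptor, was 2.00-fold lower with genistein (adjusted p = 0.0156), and Crym, a thyroid hormone binding protein, was 2.17-fold lower (adjusted p = 0.0368). Between isoflavones, a probe set of Gpat4, an enzyme of triacylglycerol synthesis that is not the one representing the gene, was 1.49-fold lower with genistein (adjusted p = 0.0344). Prlr was called higher with genistein on 3 probe sets, with log2 changes of 2.48, 3.22 and 3.38.

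The test of shared direction was chosen only after the result was seen. Of the 60 probe sets called with genistein, 55 moved the same way with daidzein, which shares its control arrays. With the controls split so that the isoflavones shared none, the 60 probe sets of lowest p with genistein were chosen anew in each split, so they need not be the 60 called. The median over 10 splits was 61.67% of them moving the same way (50 to 73.3%), and the exact permutation p over 56 relabelings had a median of 0.214 (0.107 to 0.571, one-sided). A shared effect beyond the shared controls therefore stays open. The covariance of both effects was 0.0288, within the range from residuals shuffled between the diets (mean 0.0241, 0.00844 to 0.0444). With split controls its median was 0.00814 (0.00321 to 0.0143).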
